A study of Mus musculus with 2 samples.

How the data were processed

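Total RNA of the SoNar-high and the SoNar-low population, sorted from bone marrow of mice with B-ALL, was labelled with Cy3 from 1 µg of RNA and hybridised to 1 array each, per the labels' protocols. The deposited scanner files give 1-colour intensity values per spot, extracted with Agilent Feature Extraction version 11.0.1.1 per the file headers, while the submitters' processing notes name version 9.1. Per the file headers the processed signal is a background-subtracted intensity, not scaled between arrays. The series matrix deposited by the authors holds log2 values. Its columns had the same rank order as the scanner signals (Spearman's rho 1.000 and 0.9998 across probes), a median of 5.90 on both arrays and sorted values that differed by at most 0.04, as quantile normalization gives. Its direction was the same as that of the scanner files, and how it was centred was not given in the sources used here; it was used as an alternative.

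Control spots and spots with a non-uniformity flag (1 on the SoNar-high array, 350 on the SoNar-low array) or a population outlier flag (189 and 156) were left out, and no spot was saturated. Replicate spots of a probe were averaged on the log2 scale, which left 39085 probes. The log2 processed signal minus each array's 75th percentile was the main value. RefSeq accessions of the array design were matched without versions to current symbols through a gene table of assembly GRCm38, used for names only: 27115 probes matched 20618 genes and 11970 probes had no symbol. No coordinates are given, because the build of the array design differs from that table's. A gene's difference was the mean, over its probes well above background on both arrays, of the SoNar-high minus the SoNar-low value. A gene was called at a difference of at least 2-fold, a rule of size with no p-value. Genes whose probes were all not well above background on 1 array got a bound: the bright array's value over the higher of the dim array's lowest signal well above background and the dim probe's own.

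Before the data were examined 40 gene lists were fixed, and 39 had at least 3 measured genes. For each, the median difference was set among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The named genes were fixed by rule at the same time, among genes with a symbol that is not accession-like: the 12 largest differences each way with probes of 1 direction, the 3 largest bounds each way, the 2 highest and 2 lowest members of each list, and always Mycn, Myc, Creb1, Pdhx, Pdk1, Ldha and Ptprc. Some genes that the rule names are not reported here. Other genes are named as chosen after their values were seen. Lists of genes of 10 tissues other than bone marrow were written after the pattern was noticed. For these, all probes entered, dim ones included. To give bounds in place of differences against background, both arrays were then raised to the higher of their 2 scaled lowest signals well above background, and the count of 2-fold differences among probes at least 2-fold above it on 1 array was set among 10000 random sets matched on the brighter array's level in 20 bins; this was chosen after the result was seen.

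The precision that the arrays give came from 399 probes printed as 10 spots, of which 197 were well above background on both arrays. The alternatives fixed beforehand were normexp background correction (offset 50; on the median spot signal, in place of the mean signal that had been planned), scaling to the median or to the 75th percentile over probes well above background on both arrays, quantile normalization, loess on the level (span 0.3), no filter on dim probes or a stricter one (the brighter 50% of probes well above background on both arrays), the brightest probe of each gene, outlier spots kept, the series matrix, thresholds of 1.5-fold and 3-fold, lists without their most changed gene, random lists not matched on level, and a background call at 3 SD of the 153 negative control spots. Added after seeing the data were centring on the median gene, genes with several probes only, and leaving out the brain and lung genes.

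The gene and list steps were tested on simulated data made from these arrays' levels for the comparison of SoNar-high with SoNar-low, over 10521 genes. Of 100 genes raised and 100 lowered 3-fold, 100 and 100 were called, with 0 of 10301 unchanged genes. A list of 20 genes shifted by 0.5 stood at percentile 100, and 9 of 200 unshifted lists fell outside the central 95% of random lists. The simulated error was that between spots alone (SD 0.11 per array), far under the 2-fold cut, so these calls were nearly certain. It left out the spread between probes of a gene (median SD 0.32) and any dependence on level, and it says nothing of the error between samples. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.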

Results

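Leukaemia cells that differ in their NADH/NAD+ balance were profiled on microarrays. SoNar is a genetically encoded fluorescent sensor that binds NADH and NAD+ in the cytosol, and a higher ratio of its emission under violet to that under blue excitation reports a higher NADH/NAD+ ratio. Mouse B-cell acute lymphoblastic leukaemia (B-ALL) cells from bone marrow, labelled as 8 weeks of age, were sorted by this ratio into a SoNar-high and a SoNar-low population. RNA of each population was hybridised to 1 one-colour Agilent whole-genome array, so there were 2 arrays and 1 per population. The sample titles read N-myc-high and N-myc-low instead; whether both names describe the same sort is open, and the groups follow the sensor's label, which the sorting description also uses. With 1 array per population no difference below has a replicate check, no test between the populations was possible, and the number of arrays limits the precision.

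Each array held 43020 non-control spots. On the SoNar-high array 19291 spots (44.8%) were well above background, and on the SoNar-low array 31352 (72.9%). The 75th percentile of the signal was 475 and 525 intensity units, and the lowest signal well above background was 46.4 and 19.7 units, in the same order. Among 197 probes printed as 10 spots and well above background on both arrays, the median SD between spots was 0.13 (log2) on the SoNar-high and 0.07 on the SoNar-low array, and a difference between 1 spot of each had a median SD of 0.15. This spread covers spots on a slide, not cultures, animals or sorts. Each array was scanned in a session of its own, so scan and population cannot be told apart.

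The first question was which genes differed between the SoNar-high and SoNar-low arrays. The genes furthest above on the SoNar-high array were Ly6h (3.60, SoNar-high minus SoNar-low on the log2 scale, a 12.1-fold difference), Rtn1, which encodes a reticulon of neuroendocrine cells (2.93), Faim2, an inhibitor of Fas-induced death (2.76), Denn2b (2.67) and Rab6b, a Golgi trafficking GTPase (2.53). The carbonic anhydrase gene Car14 (2.36), Vstm2l (2.29), Fbxl16 (2.20), the neuropeptide gene Cck (2.19), the phospholipid scramblase gene Xkr8 (2.18), Cpe, which encodes a prohormone-processing carboxypeptidase (2.15), and Trnp1 (2.14) completed the 12 largest. Furthest below were Scgb1a1, the secretoglobin of airway club cells (-3.31, a 9.90-fold difference), Iqcg (-3.05), Akap8, a nuclear anchor of protein kinase A (-3.01), Gprc5d (-2.97), Ap1g2 (-2.88) and Nkd2, a Wnt pathway antagonist (-2.80). The pluripotency factor gene Nanog (-2.78), Cyp46a1 (-2.76), the nucleolar chaperone gene Npm3 (-2.71), the splicing factor gene Tra2b (-2.70), Timm29 (-2.69) and Cyp2d11 (-2.56) followed. Each of these 24 genes had 1 probe well above background on both arrays. With their dim probes averaged in, Ly6h lay at 2.48, Cpe at 0.70, Trnp1 at 0.13, Gprc5d at -1.66 and Nkd2 at -0.67, and the other 19 values did not change.

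Over 10521 genes measured on both arrays, 253 were at least 2-fold higher and 462 at least 2-fold lower on the SoNar-high array, so 35.4% of the genes past 2-fold were higher. The median gene stood at 0.22, and list medians below are given relative to it, while values of single genes are not. Across genes, which are not independent replicates, the arrays correlated with r = 0.969. The counts depended on the processing, and the first 2 alternative scalings moved every gene by 0.57 and -0.30. Median scaling, which put the median gene at 0.79, gave 3380 higher and 140 lower (96.0% higher), and the 75th percentile over probes well above background on both arrays, which put it at -0.07, gave 61 and 853 (6.67%). Quantile normalization gave 350 and 386 (47.6%), loess on the level 118 and 530 (18.2%), normexp 72 and 241 (23.0%), the series matrix 430 and 359 (54.5%), the stricter filter on dim probes 141 and 111 (56.0%), and centring on the median gene 70 and 742 (8.62%).

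**Figure D1:**
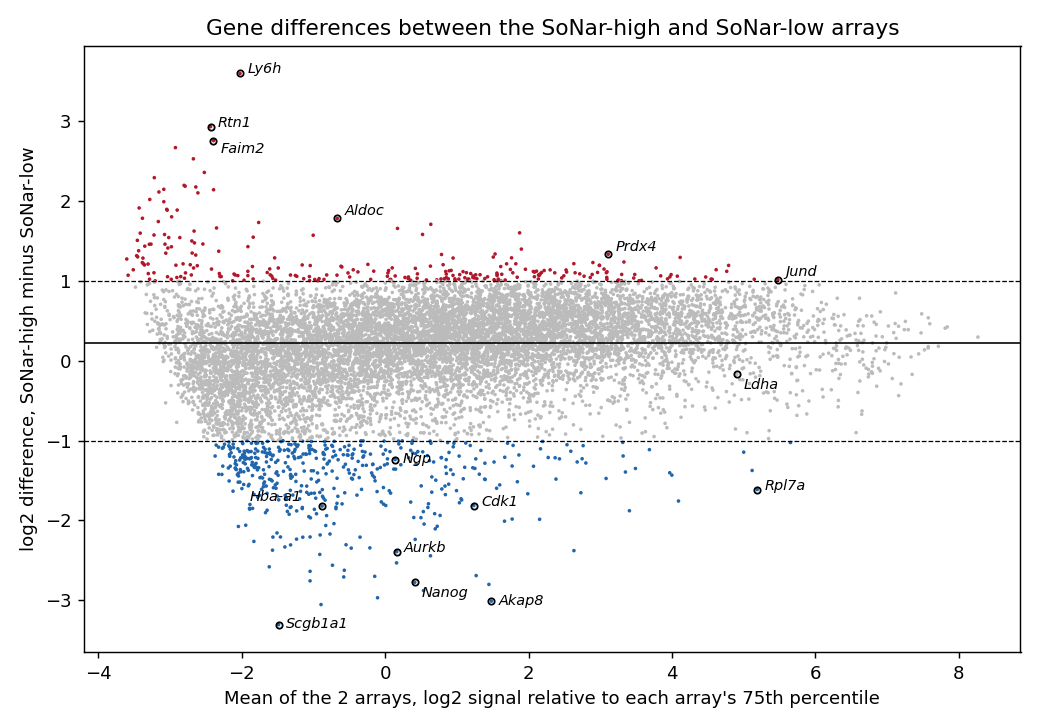
Log2 difference of each of 10521 genes (vertical axis, SoNar-high minus SoNar-low) against its mean log2 signal on the 2 arrays relative to each array's 75th percentile (horizontal axis). Red points are the 253 genes at least 2-fold higher and blue points the 462 at least 2-fold lower on the SoNar-high array, dashed lines mark 2-fold, the solid line marks the median gene at 0.22, and circles mark named genes from Ly6h (3.60) to Scgb1a1 (-3.31).

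Probes of one gene often disagreed, with a median SD of 0.32 between them. Of 2394 genes with several measured probes, 95 had at least 1 probe 2-fold higher but only 4 had all probes 2-fold higher, and 176 had at least 1 probe 2-fold lower but only 6 had all. In 117 of those 176 another probe of the gene lay above 0, and in 30 of those 95 another probe lay below 0. The 4 genes higher by every probe were Tmed9, a cargo receptor of the secretory pathway (1.60), the chemokine gene Ccl27a (1.57), the stathmin gene Stmn4 (1.16) and the thioesterase gene Lypla2 (1.02). The 6 lower by every probe were the mitotic kinase gene Cdk1 (-1.81), Krtap20-2 (-1.66), Banp (-1.51), Cnnm3 (-1.46), Marchf2 (-1.38) and the ribosomal protein gene Rps3a1 (-1.38); these 10 genes were picked out after their values were seen. Of the calls, 242 of the 253 higher and 430 of the 462 lower genes rested on 1 probe.

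Many more genes were seen on the SoNar-low array alone. There, 5453 genes were well above background while all their probes were not on the SoNar-high array, against 11 the other way, and 432 and 11 of them differed by at least 2-fold against the other array's detection floor. The scaled floors were 0.0998 on the SoNar-high and 0.0377 on the SoNar-low array. Genes seen on the SoNar-high array only thus passed 2-fold almost by construction, so 11 of 11 carries little information. The unequal floors also favour genes seen on the SoNar-low array only, so 5453 against 11 does not by itself show a difference of the populations. Among genes with a symbol that is not accession-like, the largest bounds for the SoNar-high array were Tceal3 (at least 10.7-fold higher), the synaptic vesicle gene Syt1 (at least 7.64-fold) and the phospholipid flippase gene Atp8b1 (at least 7.05-fold). For the SoNar-low array they were the lysozyme gene Lyz1 (at least 9.58-fold, uncertain because its near-identical copy Lyz2 shares most of the sequence), the lung surfactant gene Sftpa1 (at least 8.37-fold) and Zfp982 (at least 7.70-fold). The scanner software's call was replaced by a net signal of 3 SD of the negative control spots as an alternative, and these counts became 3797 and 211.

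Genes of the lung stood lowest and genes of the brain highest of the 10 tissue lists. Over all probes, dim ones included and so in part against background, the lung list had a median of -1.91 and the brain list one of 0.72, while 8 lists of other tissues had medians from -0.94 to -0.09. Among random sets of probes matched on level the lung list stood at percentile 0 and the brain list at 100, but heart (0.99) and kidney (2.47) genes were low too. With both arrays raised to the higher detection floor, 12 of 16 lung probes at least 2-fold above that floor on 1 array were at least 2-fold lower. Of 27 brain probes 12 were at least 2-fold higher and 4 lower, and of 38 probes of the other tissues 9 were lower and 0 higher. Over all named probes as bright, 8.51% were lower and 2.42% higher. Of 26 lung genes with a probe, 19 were well above background on the SoNar-low array only, against 12 of 18 heart, 11 of 18 kidney and 10 of 18 testis genes; the 6 lung genes measured on both arrays lay 3 above and 3 below 0, with 2 at least 2-fold lower. Of 41 brain genes with a probe, 26 were measured on both arrays, and 13 of these were at least 2-fold higher and 1 at least 2-fold lower on the SoNar-high array, with 18 above and 8 below 0; over all their probes 10 of the 13 stayed past 2-fold. Rtn1, Cck and Cpe above belong to the brain list, and Scgb1a1, Sftpa1 and Lyz1 to the lung list; both lists were written after this pattern was noticed. Without the genes of both lists 240 genes were at least 2-fold higher and 459 lower. That step kept 10489 of the 10521 measured genes, so the counts could hardly move. They cannot show whether RNA of brain or lung lies behind other calls.

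**Figure D2:**
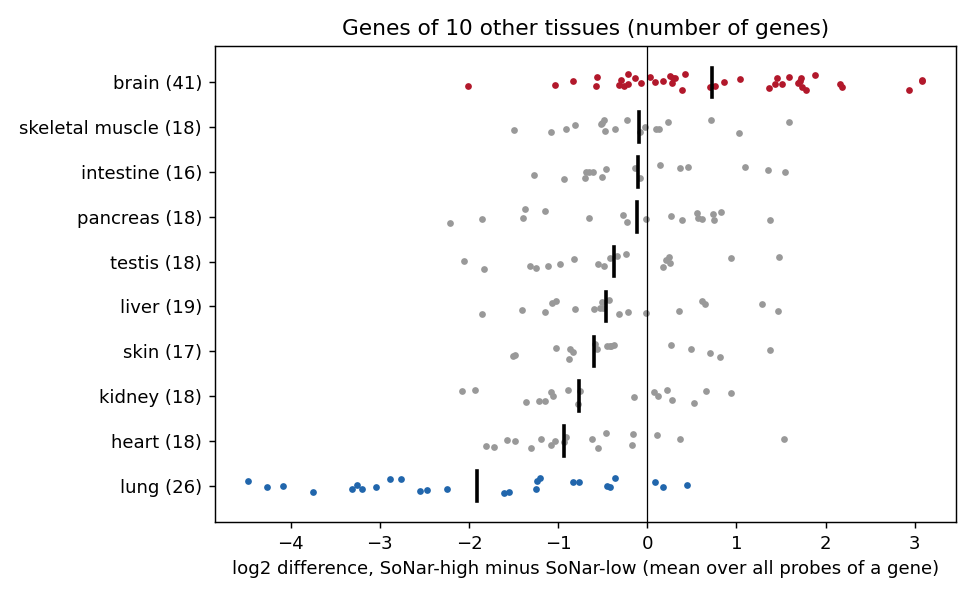
Log2 difference, SoNar-high minus SoNar-low, of genes typical of 10 tissues other than bone marrow (horizontal axis; each point is the mean over all probes of 1 gene, and the number of genes stands beside each tissue). Black bars are medians over probes; lung (blue, -1.91) lay lowest and brain (red, 0.72) highest of the 10 lists.

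The sort was made on a metabolic sensor, so genes of NADH-producing and NADH-consuming pathways were compared next. Glycolysis genes as a group stood with the median gene (median 0.02, percentile 50.03 among 10000 random lists of the same size and level, here and below as a description of these arrays). Of 24 measured members 1 was at least 2-fold higher, Aldoc, an aldolase gene that is also on the brain list (1.78); the neuronal enolase gene Eno2 (0.90) was next, while the monocarboxylate carrier genes Slc16a3 (-0.75) and Slc16a1 (-0.55) were lowest. Ldha, which encodes the muscle-type subunit of lactate dehydrogenase, was at -0.17 with 3 probes between -0.55 and 0.17. TCA cycle genes had a median of 0.26 (percentile 83.0), with 14 of 18 above the median gene and none past 2-fold, from Sucla2 (0.91) and Idh3a (0.71) to Pcx (-0.23). Respiratory complex I genes had a median of 0.18 (percentile 65.5), with 27 of 36 above the median gene, among them Ndufa1 (0.79) and Ndufs7 (0.77). Before the median gene was subtracted, the TCA cycle and complex I medians were 0.48 and 0.40. The middle of their level-matched random lists was 0.38 and 0.37, so these counts largely follow the level of the genes.

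Pyruvate dehydrogenase, its regulators and pyruvate import had a median of 0.05 over 12 genes (percentile 61.3), from the phosphatase gene Pdp1 (0.72) and the dihydrolipoamide dehydrogenase gene Dld (0.66) to the pyruvate carrier gene Mpc2 (-0.70). Pdhx, which encodes the component that anchors dihydrolipoamide dehydrogenase in the complex, was at 0.06, and Pdk1, whose kinase inactivates the complex, was at 0.58. NADH shuttle genes had a median of 0.22 (percentile 81.9), with the aspartate aminotransferase gene Got1 at 1.04, the aspartate-glutamate carrier gene Slc25a12 at 0.72 and Got2 at -0.19. Fatty acid oxidation genes had a median of 0.22 (percentile 89.3), with Acaa2 at 0.73. Complexes III and IV with cytochrome c lay at 0.06 (percentile 31.6; Cox6c 0.93, Cox15 -0.47) and ATP synthase at 0.07 (percentile 22.4; Atp5e 0.77, while 2 probes of Atp5c1 lay at -1.70 and 0.28). The genes of NAD synthesis and use lay at 0.01 (percentile 43.2), with Nampt, the rate-limiting enzyme of NAD salvage, at 0.95 and the deacetylase gene Sirt2 at -0.80.

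Mitochondrial biogenesis genes had a median of 0.10 (percentile 67.6). Ppargc1a, a coactivator of mitochondrial biogenesis, was at 1.60 and Ppargc1b at -0.72. The 1 measured probe of Ppargc1a was dim, with scaled signals of 0.163 on the SoNar-high and 0.054 on the SoNar-low array. The detection floors were 0.0998 and 0.0377 in the same order. Creb1, a cAMP-responsive transcription factor, was at 0.62 by its 1 measured probe. A second Creb1 probe was not well above background on the SoNar-high array. Mitochondrial ribosomal protein genes had a median of 0.08 (percentile 15.02), with Mrpl1 (-1.13) and Mrps5 (-1.11) at least 2-fold lower and Mrps16 at 0.99. The pentose phosphate pathway lay at 0.08 (percentile 34.3; Rpe 0.88, Pgls -0.40), serine and one-carbon metabolism at 0.09 (percentile 57.3; Mthfd2l 0.81, Tyms -0.80), glutamine and amino acid supply at -0.02 (percentile 18.1; Glul 0.65) and cholesterol and fatty acid synthesis at 0.06 (percentile 77.1; Msmo1 0.83, Scd1 -0.78). Hypoxia-responsive genes lay at 0.15 (percentile 72.4), with the glucose transporter gene Slc2a1 at 0.84 and the oxygen sensor gene Egln1 at -0.88.

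Growth and cell cycle genes came next. The Mycn probe was not well above background on either array, so these arrays gave no measured difference in the gene the sample titles name. The Myc probe was well above background on the SoNar-low array only (25.1 units, against 9.38 on the SoNar-high array, which lay under that array's detection floor), and no fold was given. Cytosolic ribosomal protein genes had a median of -0.12, below 10000 of 10000 random lists, with 50 of 78 under the median gene; Rpl7a was at -1.61 over 4 probes spanning -2.86 to -0.23, and Rplp1 at 0.67. With no filter on dim probes that median was 0.056, and again lay below 10000 of 10000 random lists. Ribosome biogenesis and MYC-regulated genes lay at -0.04 (percentile 2), from Nop2 (0.85) to Utp20 (-2.05), but at percentile 38.7 with the brightest probe of each gene. G1/S genes lay at 0.14 (percentile 56.7; Prim1 0.87, Cdc6 -1.36) and G2/M genes at 0.16 (percentile 62.1). Within the G2/M genes Plk1 (0.85) and Aurka (0.85) were on the other side of 0 from Aurkb (-2.39) and Cdk1 (-1.81).

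B-lineage genes showed no common direction. Ptprc, which encodes the CD45 phosphatase, was at -0.22. Genes of pro-B and pre-B cells had a median of -0.03 (percentile 39.4), with the B-lineage factor gene Ebf1 at 0.98, the adaptor gene Blnk at 0.77 and Ikzf3, a zinc finger factor of the Ikaros family, at -1.33. Mature B-cell genes lay at 0.11 (percentile 77.9), from Ly6d (1.06) and Cd52 (0.96) to the sialic acid receptor gene Cd22 (-1.10). Plasma cell genes lay at -0.40 (percentile 16.1; Prdm1 -1.43, Xbp1 0.60) and stem and progenitor genes at -0.17 (percentile 29.8; Bmi1 0.74, Cd44 -0.25).

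Genes of several other marrow cells were lower on the SoNar-high array relative to the median gene. Neutrophil genes had a median of -0.62 (percentile 0.01), with 15 of 16 under the median gene, from the granule protein gene Ngp (-1.24) and Retnlg (-0.98) to S100a9 (0.21) and Prtn3 (0.37). Monocyte and macrophage genes lay at -0.73 (percentile 1.28; Csf1r -1.19, C1qb -1.09, Mrc1 0.62), T and NK cell genes at -0.97 (percentile 0.04; Cd4 -1.66, Cd3e -1.20), and both 4-gene lists lower still: erythroid genes at -1.29 (percentile 0.18; Hba-a1 -1.82, Ermap -1.61, Hemgn 0.89) and stroma and endothelium genes at -1.02 (percentile 1.14; Kdr -1.48, Lepr -0.97). Thy1 (1.37), also a brain gene, and Lck (1.00) went the other way among the T and NK genes, and with the stricter filter on dim probes that list stood at 0.16 (percentile 74.2). Dendritic cell genes lay at 0.11 (percentile 61.0; Ccr9 0.95, Siglech -0.90), and of the platelet genes 1 was measured and 5 were seen on the SoNar-low array only, so no median was taken.

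Adhesion and homing genes, many of them shared with those cells, had a median of -0.42 (percentile 2.26), with the beta-2 integrin genes Itgb2 (-1.10) and Itgal (-1.05) lowest and Itga6 (0.85) and Cd47 (0.72) highest; with the stricter filter on dim probes the median was 0.21. BCL2 family genes, which set the threshold for apoptosis, had the highest median of the 39 lists with at least 3 measured genes under the main scaling, at 0.37 (percentile 99.1), led by the death-promoting genes Bmf (1.08) and Pmaip1 (0.74) and with Bid (-0.34) lowest; the survival genes Mcl1 (0.68), Bcl2l1 (0.63) and Bcl2 (0.60), picked out after their values were seen, lay nearly as high as Pmaip1. Without Bmf this percentile was 88.6. Immediate early and CREB-responsive genes lay at 0.11 (percentile 84.9; Jund 1.01, Jun 1.00, Pde4b -0.40) and genes of the unfolded protein response at 0.13 (percentile 81.7; Dnajb9 0.91, Herpud1 0.90, Sesn2 -1.57). Antioxidant enzyme genes lay at -0.02 (percentile 12.4), with the peroxiredoxin gene Prdx4 at 1.33, the catalase gene Cat at -1.19 and the haem oxygenase gene Hmox1 at -1.11. The remaining medians were those of p53 targets (0.13, percentile 76.5), interferon-stimulated genes (0.01, percentile 76.8), heat shock and chaperone genes (0.01, percentile 22.6) and drug transport and response genes (0.13, percentile 71.1; Abcc4 0.97, Tpmt -0.93).

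**Figure D3:**
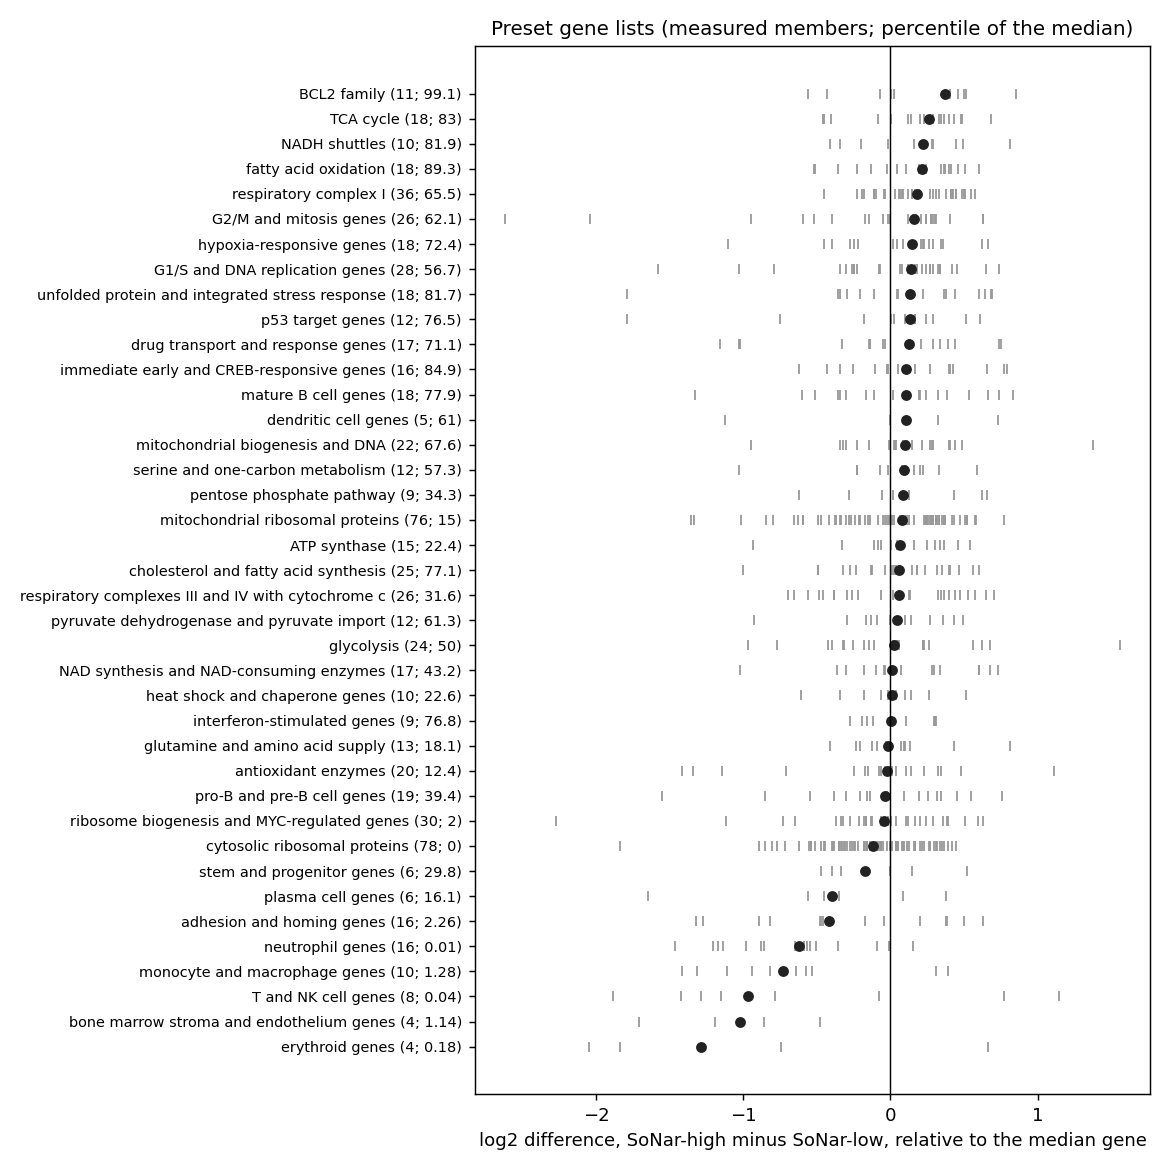
Log2 difference, SoNar-high minus SoNar-low, of the measured members (ticks) and the median (dots) of 39 gene lists, relative to the median gene (horizontal axis; the number of measured members and the percentile of the median among 10000 matched random lists stand beside each name). Lists of other marrow cells fill the lowest places, from erythroid genes (-1.29) to neutrophil genes (-0.62), and the BCL2 family (0.37) the highest.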

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

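All tests on brain and lung genes, the tests on the source of the neutrophil genes and the use of the stricter filter on the blood cell lists were chosen after those results were seen; the tests of the detection floor, of nonspecific hybridisation and of loess on the neutrophil list were written before theirs. In data outside the comparison of genes measured on both arrays, 19 of 26 lung genes were well above background on the SoNar-low array only (12 of 18 heart and 11 of 18 kidney genes were too) and 3 brain genes on the SoNar-high array only (5 on the SoNar-low array only). Another signal outside it came from probes without a gene symbol, of which 3833 were well above background on both arrays and had a median difference of -0.07, with 14.5% at least 2-fold lower and 1.98% higher, against 0.23, 4.62% and 2.57% for probes with a symbol.

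Genes of lung were lower and genes of brain higher on the SoNar-high array, in cells sorted from bone marrow. Both arrays were raised to the higher detection floor, which turns differences against background into bounds. Of 16 lung probes bright enough to differ by 2-fold, 12 were at least 2-fold lower, and 12 of 27 brain probes were at least 2-fold higher. Of 10000 random sets of probes matched on the brighter array's level, 0 held as many of either. The most in 1 random set was 7 lower for lung and 5 higher for brain. Both lists were written after the pattern was noticed and hold Rtn1, Cck, Cpe, Scgb1a1, Sftpa1 and Lyz1, so these counts in part restate it. A probe could also pass this filter through 1 array alone. The random sets thus cannot settle whether a bias of dim probes had a part. Of 38 probes as bright from the 8 other tissue lists 9 (23.7%) were lower and 0 higher, against 8.51% and 2.42% of all named probes as bright. Sftpc, Sftpa1, Sftpb, Cyp2f2 and Cbr2 were all seen on the SoNar-low array only, so RNA of lung on that array is a candidate explanation. The lung list genes Lamp3 (0.44), Hopx (0.18) and Napsa (0.09), well above background on both arrays, did not differ by 2-fold. Lamp3 and Napsa had scaled signals of 14.1 and 18.6 on the SoNar-low array, where Lyz1 and Sftpa1 reached 1.16 and 0.83. Added RNA of that size would hardly move Lamp3 or Napsa, so they cannot count against lung RNA. Hopx, at 1.27, was nearer that size. Of the 27 brain probes 4 were at least 2-fold lower. Of 26 brain genes measured on both arrays 8 lay below 0, among them Snap25 (-1.04), Mog (-0.84) and Syp (-0.57). Snap25, Mog and Syp had scaled signals of 2.78, 1.00 and 1.99 on the SoNar-low array, a level that could hide an addition on the other. Their values cannot decide. Camk2a, also below 0 at -0.33 by its 1 probe measured on both arrays, lay at -2.01 over its 2 probes. Its scaled signals were 0.26 on the SoNar-low and 0.064 on the SoNar-high array, a level that would hide less. That is 1 gene whose probes differ, and RNA of brain on the SoNar-high array stays open. Expression of the lung and brain genes by the sorted cells was not tested. If the sort also selected for the sensor's fluorescence, which was not checked here, it would remove cells without the sensor but not RNA that entered later.

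More probes were well above background on the SoNar-low array, 28416 against 17215. With the higher of the 2 detection floors set for both arrays the ratio of these counts was 1.14 in place of 1.65, so a lower floor on the SoNar-low array may account for most of the gap but left a rest. Probes of olfactory and vomeronasal receptors, which blood cells hardly express, had a ratio of 1.81 (95% bootstrap interval over probes 1.61 to 2.09), against 1.104 for other named probes. Nonspecific hybridisation on the SoNar-low array would give this. However, 8.86% of the receptor probes passed the common floor on the SoNar-high array, against 55.4% of other named probes. A level-dependent offset between the arrays weighs most on probes so near the floor, so this test cannot tell it from nonspecific hybridisation. With 1 array per population neither a lower floor nor nonspecific hybridisation can be set apart from a difference of the populations.

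Genes of neutrophils, monocytes, T and NK cells and erythroid cells were lower on the SoNar-high array relative to the median gene. The neutrophil list stayed at percentile 0 after loess on the level and at -0.78 (percentile 0) with the stricter filter, which kept 10 of 16 genes, and this argues against a bias of dim probes there. The T and NK list lay at percentile 0.04 after loess, but the stricter filter kept 3 of its 8 genes, at 0.16 (percentile 74.2), and fewer than 3 each of the monocyte and erythroid genes, so for these lists such a bias stays open. Other blood cells in the SoNar-low sample could account for the lower neutrophil genes. Of 6 abundant ones (S100a8, S100a9, Ngp, Camp, Lcn2 and Ltf) 6 lay under the median gene. S100a9 did so by less than the SD between spots, which leaves 5. These 6 are among the 16 measured genes of the list, 15 of which lay under the median gene. Their count thus restates the shift of the list and cannot tell this candidate from others. Lung RNA with its blood cells is another candidate. Of 32 lung probes the 16 bright enough to differ by 2-fold, raised to the common floor, lay at -2.29 relative to all named probes as bright. A probe could pass this filter through 1 array alone, and the value is not matched on level, so it cannot decide. Of 4 genes made in marrow precursors 3 (Ctsg, Elane and Mpo, not Prtn3) were also under the median gene, which this candidate does not predict. All 4 belong to the neutrophil list, of which 15 of 16 measured genes lay under the median gene. This count thus largely restates that result and cannot decide either. A difference between the leukaemia cells themselves stays open and untested. The sort would remove cells without the sensor only if it also selected for the sensor's fluorescence, which was not checked here.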

How the results depend on the processing

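Centring on the median gene, genes with several probes and the left-out tissue lists were chosen after seeing the data. No paired analysis was possible because there was 1 array per population. Of 32 alternative counts and spreads 12 stayed within 1.5 times; 1 of these, the sum of genes seen on 1 array only, hid a shift of its parts from 11 to 211 for the SoNar-high and from 5453 to 3797 for the SoNar-low array with 3 SD of the negative controls. The rest follow, as higher and lower: normexp 72 and 241, median scaling 3380 and 140, the 75th percentile over probes well above background on both arrays 61 and 853, no filter on dim probes 1885 and 2542, the stricter filter 141 and 111, centring on the median gene 70 and 742, genes with several probes 11 and 32, 1.5-fold 2145 and 1070, and 3-fold 31 and 133; the higher count alone moved with loess (118) and the series matrix (430). The thresholds, scalings and filters move counts by their construction; for normexp, loess and the series matrix the cause was not tested. Of 565 alternative list medians 543 moved by less than their interval, and 75, from 27 lists, lay on the other side of 0, among them T and NK cell genes (0.16) and adhesion genes (0.21) with the stricter filter. Cytosolic ribosomal proteins stood at 0.056 with no filter on dim probes, and at -0.24 with quantile normalization, -0.29 with the stricter filter and -0.23 with the series matrix. Mitochondrial ribosomal proteins stood at -0.11 with quantile normalization, -0.075 with loess, 0.25 with no filter, -0.064 with the stricter filter and -0.12 with the series matrix. With no filter the TCA cycle stood at 0.44, serine metabolism at 0.28, glutamine supply at 0.16, cholesterol synthesis at 0.24, G1/S genes at 0.30, G2/M genes at 0.33, interferon-stimulated genes at -0.20 and antioxidant enzymes at 0.18. Interferon-stimulated genes stood at 0.37 with quantile normalization and 0.45 with the series matrix, and with the stricter filter ATP synthase stood at -0.10 and antioxidant enzymes at -0.20; with several probes only, pyruvate dehydrogenase genes stood at 0.38. The neutrophil list stayed between percentiles 0 and 0.13, the monocyte list between 0.55 and 16.2 and the BCL2 family between 85.0 and 99.3, but other lists ranged widely: NAD synthesis and use 27.0 to 97.2, pyruvate dehydrogenase genes 46.5 to 97.3, NADH shuttles 44.9 to 96.8, the TCA cycle 39.0 to 91.4, glycolysis 9.73 to 67.5, adhesion genes 2.18 to 82.8 and T and NK cell genes 0 to 74.2. No named gene past 2-fold changed sign, and 928 of 2069 alternative values of named genes moved by more than the spread between spots or probes. All 12 of the highest and 12 of the lowest genes stayed past 2-fold under every scaling, normexp, loess and the series matrix; with no filter on dim probes 10 and 11 did. The stricter filter left 0 of the 12 highest and 4 of the 12 lowest genes measured, and these 4 stayed past 2-fold. Dim genes were limited by the SoNar-high array, whose 75th percentile was 10.2 times its lowest signal well above background, against 26.7 times on the SoNar-low array.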
